A study of Homo sapiens with 2 samples.

How the data were processed

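Chromatin of KBM7 cells was crosslinked with formaldehyde, sheared and immunoprecipitated with an antibody against H3K9me3 (Abcam ab8898) or with IgG, per the labels, and sequenced as Illumina libraries. The study holds 1 H3K9me3 library and 1 IgG library. The processed values analysed here are those of the H3K9me3 library, and the IgG library was not used here. Bowtie2, MACS and the hg19 build are named, per the submitters' processing notes, without versions or roles, and read filtering, read extension and the use of the IgG library in peak calling are not given in the sources used here.

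The authors deposited a table of gene intervals with a read count per interval, not normalised, and the interval length in kb, which equals the span of the coordinates. The deposited gene score is the read count divided by the interval length in kb, checked in every interval with a largest difference of 3.03e-06. It is not scaled to the depth of the library and not corrected for IgG or copy number, so it is comparable between genes of this library only. The deposited peak list gives the chromosome, start and end of each peak, with no height, fold or significance. All 126965 peaks lie on a grid of 150 bp. Counts are reads, not molecules, and 54.7% of gene intervals overlap another one and so share reads. The intervals behind 3 genes (TMPRSS3, MX2 and PARP1) are longer than 2.4 Mb and were kept, and left out as an alternative.

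For each symbol the interval with the highest score was used (280 symbols had more than 1). Peak cover, peak number and the peaks at start sites were computed per gene, with an overlap of 1 bp or more. Chromosome length was the highest coordinate in the data. Gene lists, 28 in all, were compared with 10000 random lists of the same size drawn from all nuclear symbols, and a list was called when its median score or its share of genes with a peak lay outside the middle 95%. Percentiles describe this library and are not p-values, and random single genes ignore that members of a list are neighbours, for which lists shifted as a whole along the genome were added. Random placement of peaks kept chromosome and width, with 100 draws. Score intervals are exact Poisson and share intervals exact binomial (Clopper-Pearson) at 95%, and cover counting error only. Bootstrap intervals drew genes 1000 times for cover along the gene body, intervals 1000 times for the scores around the 20 highest, 5 Mb blocks 500 times for chromosome 8, intervals 500 times for other corrected scores and intervals 200 times for the overhang. Gene types came from a table of human genes on GRCh38.p14, used for names and types only: 22159 of 35812 symbols had a type and 18695 were matched to protein-coding genes. A correlation across genes between score and peak cover is not reported here. With 1 library no p-value was computed and no comparison between groups of samples was made; the tests named in the closing section set values within this library against random lists, random placements or bounds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

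The gene lists, the main comparisons, a first set of alternatives and the rule for named genes were chosen before the data were examined. The rule takes the 20 highest scores, the 3 highest members and the lowest member of each list, the 5 widest peaks and 10 fixed reference genes. It also asked for the 10 peaks with the highest fold, and some alternatives for the most significant peaks. Neither could be applied because the peak list used here gives neither value, and selections by peak width took their place. Genes and regions outside the rule are said to have been chosen after the data were seen. Lists of developmental transcription factors and of immunoglobulin and T cell receptor segments, the bounds on chromosome 15, the correction for short intervals and the alternatives for chromosomes 8 and 15, protein-coding symbols and shifted lists were added after the data were seen.

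The list comparison was tested on simulated data, 100 lists of 25 genes per fold among 35812 genes. Lists left as drawn fell outside the middle 95% in 7 of 100 cases, and lists raised 1.25, 1.5 and 2 times in 17, 40 and 88. Lists of about 25 genes that differ less than 2 times can thus be missed. The simulated lists were single genes drawn at random and none was lowered, so these figures do not cover lists of neighbouring genes or lowered lists.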

Results

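H3K9me3, the histone mark of constitutive heterochromatin and of silenced repeats and gene clusters, was mapped by chromatin immunoprecipitation and sequencing in KBM7 cells, a near-haploid line from a chronic myeloid leukemia. The study holds 1 H3K9me3 library and 1 IgG control library. Values of the IgG library were not analysed here, so every value below describes the H3K9me3 library and has no replicate and no control beside it. Reads were given for 40237 gene intervals with 35812 symbols. They sum to 78512210 reads, a sum that counts some reads more than once because 54.7% of the intervals overlap another one; the total depth of the library is not given in the sources used here. The median interval held 272 reads (25th to 75th percentile 36 to 1449), and 653 intervals (1.62%) held 0 reads, among them all 37 mitochondrial ones. The gene score, in reads per kb, had a median of 43.5 over symbols, with 14.4 at the 10th percentile and 147 at the 90th. Protein-coding symbols scored lower: random lists of 524 of them had a typical median of 34.3. Most protein-coding symbols thus lie below the median of all symbols, and counts of list members above or below it carry this limit. Intervals given with scores and shares cover counting error only.

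Peaks of H3K9me3 were spread over chromosomes 1 to 22 and X, and the widest lay on chromosome 8. The list held 126965 peaks that together covered 190 Mb, which is 6.25% of chromosomes 1 to 22 and X. Peak width had a median of 900 bp (25th to 75th percentile 600 to 1650) and reached 206700 bp. The widest peak lay on chromosome 8 at 46969201 to 47175900 (hg19), a stretch with no gene interval. The next was at 43603501 to 43720500 on the same chromosome, again without a gene interval. A peak of 94500 bp at 145860001 to 145954500 of chromosome 8 overlapped the zinc finger gene ZNF251, ARHGAP39, AF186192.1 and AF186192.2. The other 2 of the 5 widest lay at 43392151 to 43480650 of chromosome 8, over AC134698.1, and at 47272801 to 47343000, over no gene interval. Of the 1063 peaks of 10 kb or more, 498 lay on chromosome 8, 147 on chromosome 15 and 119 on chromosome 19. The widest peak over a gene outside chromosome 8, a position looked up after the data were seen, spanned 54600 bp at 89329501 to 89384100 of chromosome 15 and overlapped ACAN, which encodes the cartilage proteoglycan aggrecan. It lies in the part of chromosome 15 from 60 to 90 Mb, where peaks were wide in general, with a median of 3600 bp.

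Chromosomes 8 and 19 stood apart from the other autosomes, chromosome 8 by wide peaks and high gene scores and chromosome 19 by many peaks. Chromosome 19 had 84.0 peaks per Mb, 2.11 times the median of the other autosomes, and 17.8% of it lay in peaks. Chromosome 8 had 34.5 peaks per Mb, 0.813 times that median, but 15.5% of it lay in peaks, 2.78 times the median. The median peak on chromosome 8 was 2700 bp wide, against 900 to 1200 bp on the other autosomes. Gene intervals of 1 kb or more on chromosome 8 had a median score of 85.9, 2.19 times the median of the other autosomes, whose medians ran from 24.3 to 48.5. On chromosome 15 the part from 60 to 90 Mb, bounds set after the data were seen, held 90.9 reads per kb over its intervals, 2.02 times the pooled value of autosomes other than 8 and 15. The parts of chromosome 15 up to 60 Mb and beyond 90 Mb held 47.4 and 54.9 reads per kb. In the part from 60 to 90 Mb 18.0% of the sequence lay in peaks and the median peak was 3600 bp wide, against 5.93% and 900 bp up to 60 Mb. KBM7 cells are known to carry chromosome 8 and a piece of chromosome 15 in an extra copy. Neither the reads nor the scores were corrected for copy number. The rank of chromosome 8 depended on the measure, since it lay below the median of the other autosomes when peaks were counted and above that median when covered sequence was measured.

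**Figure D1:**
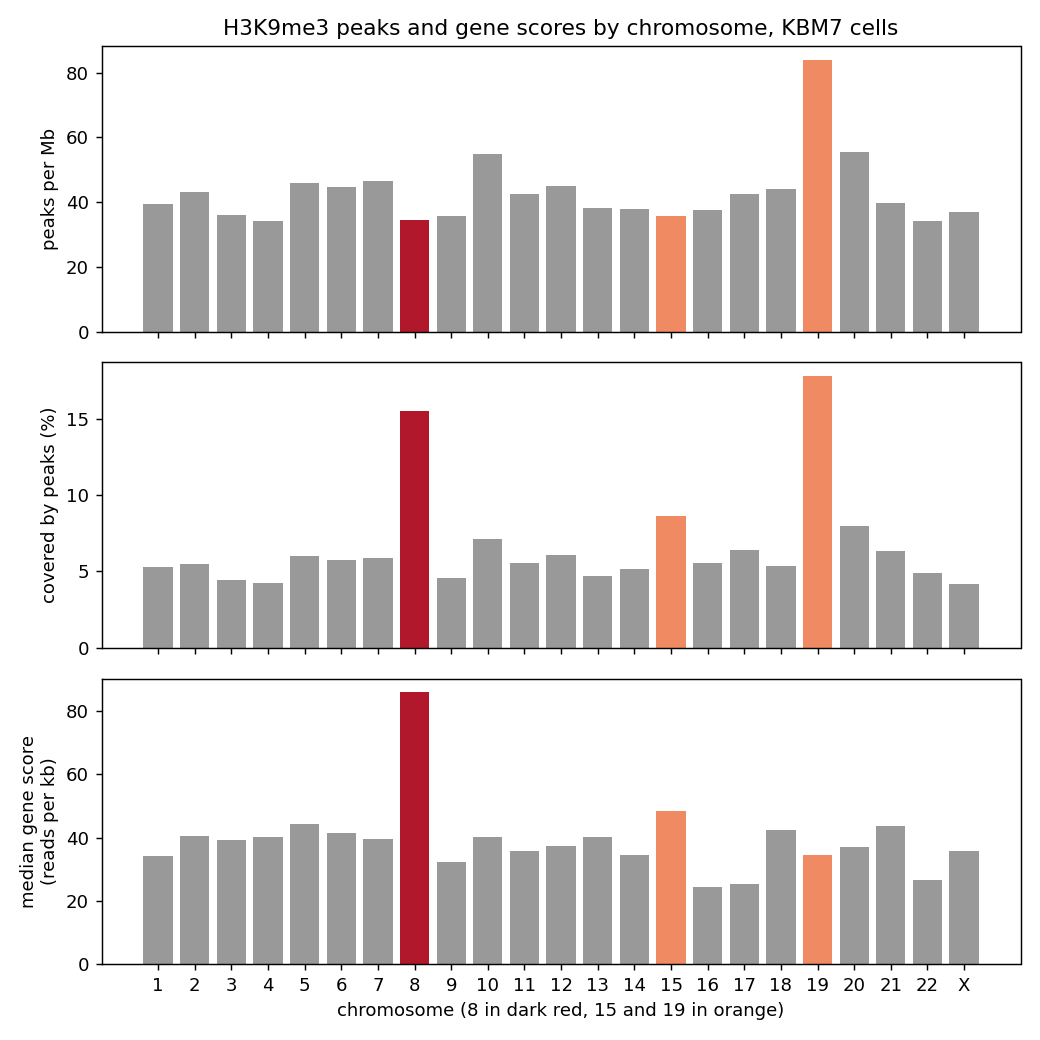
Bars show, for each chromosome, H3K9me3 peaks per Mb (top), the percent of the chromosome covered by peaks (middle) and the median gene score in reads per kb of intervals of 1 kb or more (bottom) in the 1 H3K9me3 library. Chromosome 19 has 84.0 peaks per Mb, and chromosome 8 has 34.5 peaks per Mb but 15.5% cover and a median score of 85.9.

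**Figure D2:**
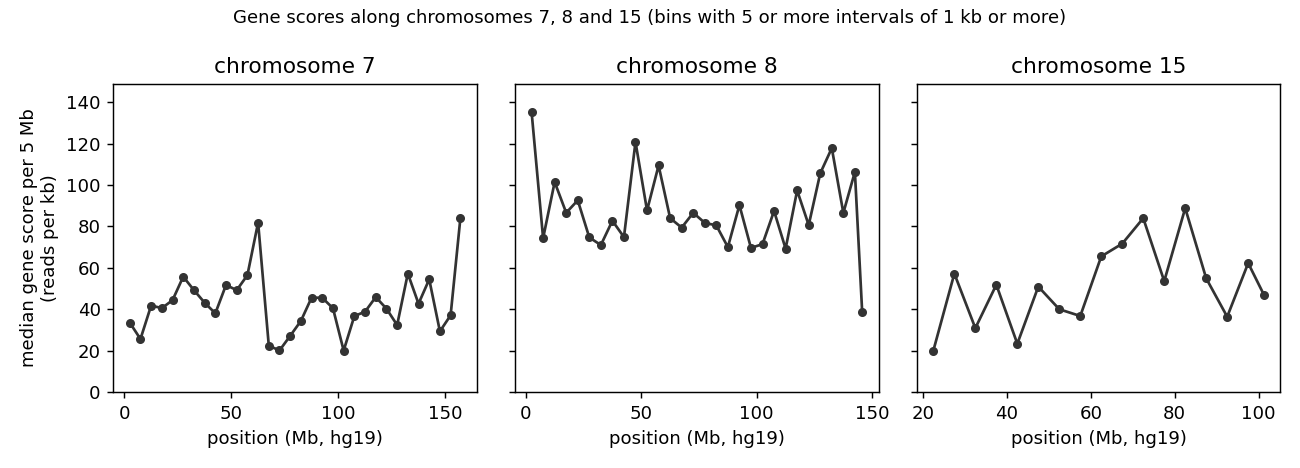
Points show the median gene score in reads per kb per 5 Mb along chromosomes 7, 8 and 15 (hg19), for bins with at least 5 intervals of 1 kb or more; chromosome 7 was added as a chromosome of similar length. The scores of chromosome 8 lie above those of chromosome 7 in most bins, and most bins of chromosome 15 between 60 and 90 Mb lie above those before 60 Mb.

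Zinc finger genes of chromosome 19 were covered by H3K9me3 over most of their length. These genes, many of which encode KRAB repressors and lie in tandem clusters, are a known target of the mark. Peaks covered on average 60.6% of the gene body of 245 zinc finger genes with a ZNF or ZFP number and 12.4% of that of the 1449 other genes of the chromosome, a ratio of 4.87. Among protein-coding symbols alone the means were 60.5% and 7.62%, a ratio of 7.94. The mean lay above that of all 10000 random lists of 245 genes from chromosome 19. A peak was present in 228 of the zinc finger genes (93.1%) and in 461 of the other genes (31.8%). Their median score was 138, against 31.6 for the other genes. By the mean the scores were 142 and 82.6, a ratio of 1.72, at the percentile 99.7 of random lists from the chromosome. Among protein-coding symbols the ratio of means was 3.55. Zinc finger genes of the other chromosomes had a mean cover of 29.9%, against 7.35% for the other genes there, a ratio of 4.07. Cover of zinc finger genes increased along the gene body. Among protein-coding zinc finger genes of 3 kb or more on chromosome 19 it was 38.3% in the first 10% of the gene and 75.2% in the last, a difference of 37.0 percentage points (31.3 to 43.0, bootstrap over 237 genes). For zinc finger genes elsewhere the difference was 19.4 points (14.5 to 24.0, 277 genes), and for the other genes of chromosome 19 it was 2.90 points (1.31 to 4.53, 976 genes). For the 15524 other genes elsewhere it was -0.656 points (-0.976 to -0.282). Genes lie in clusters and are not independent, so the bootstrap intervals of these means, which drew single genes, can be too narrow. They describe this library only.

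**Figure D3:**
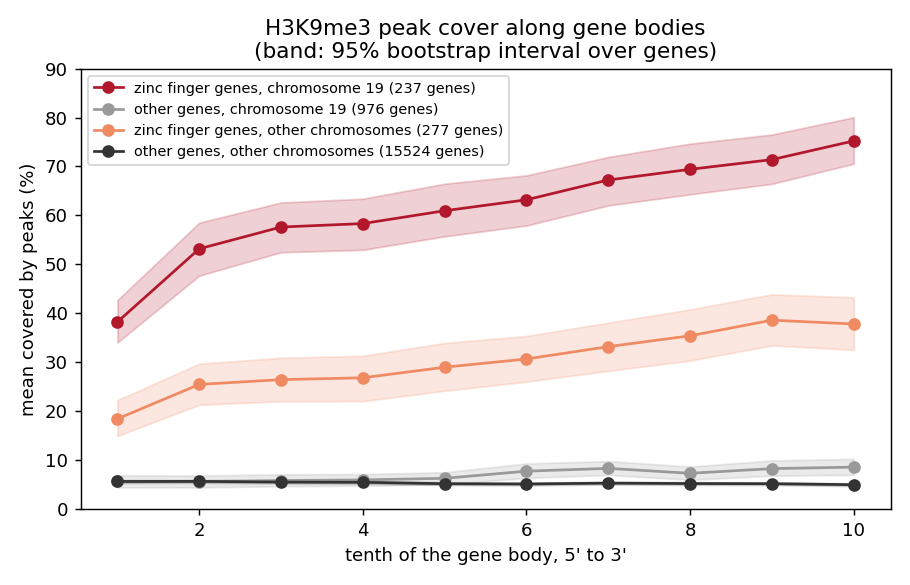
Lines show the mean percent of each 10% of the gene body covered by H3K9me3 peaks, from the 5' to the 3' end, for protein-coding genes of 3 kb or more, with 95% bootstrap intervals over genes as bands. Zinc finger genes of chromosome 19 go from 38.3% to 75.2%, and other genes stay below 10%.

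Among the gene groups, zinc finger genes, clustered protocadherins, keratins, keratin-associated proteins and olfactory receptors carried high H3K9me3 scores. The 529 zinc finger genes had a median of 115 reads per kb, and 418 of them lay above the median of all symbols and 170 above the 90th percentile. Without chromosome 19 the median of the remaining 284 was 68.7, still above all random lists. ZNF7 and ZNF572, both on chromosome 8, scored 502 (95% Poisson interval 492 to 512) and 407 (391 to 423), and ZNF792 on chromosome 19 scored 430 (415 to 444). The lowest was ZNF705D at 3.68 (2.64 to 5.00). All 49 clustered protocadherins, adhesion molecules of neurons encoded in tandem arrays on chromosome 5, lay above the median of all symbols, with a list median of 98.5. PCDHB1 scored 192 (175 to 210), PCDHB12 156 (143 to 170) and PCDHB4 132 (120 to 144), and PCDHGC5 was lowest at 73.8 (70.3 to 77.3). Intervals of the alpha and gamma arrays are nested and share reads, so their members are not separate measurements. The 55 keratins, structural proteins of epithelia, had a median of 92.4 with 50 above the median of all symbols, led by KRT10 at 191 (179 to 204), KRT9 at 144 (135 to 154) and KRT38 at 142 (130 to 154). The 93 hair keratin-associated proteins had a median of 86.7 with 81 above, among them KRTAP23-1 at 236 (174 to 311). Of the 377 olfactory receptors, odorant receptors of the nasal epithelium, 324 lay above, with a median of 84.2, and OR10H4 scored 273 (241 to 309), OR1F1 241 (211 to 274) and OR2C1 240.3 (211 to 272). Each of these 5 medians lay above those of all 10000 random lists of the same size. Against lists matched on gene length, whose medians were higher for the short olfactory receptor (67.8) and keratin-associated (61.4) genes, the 5 lists stayed above the middle 95%, keratin-associated proteins at the percentile 99.8. With the list mean in place of the median the 5 lists fell inside the middle 95% of random lists, at percentiles of 96.8, 92.0, 87.3, 95.4 and 89.5 in the order named, and protocadherins did so too, at 95.5, when lists were shifted as a whole along the genome. Random lists spread more widely by the mean: for 529 genes their middle 95% ran from 64.4 to 122, against 39.9 to 47.5 by the median.

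The short genes for microRNAs and small nucleolar RNAs had the highest medians, 161 reads per kb over 711 genes and 167 over 406 genes, above all random lists. Their median lengths were 0.088 and 0.084 kb. With the correction for short intervals their medians were 50.5 and 52.8, still above all random lists but no longer the highest, with zinc finger genes at 115. Among random lists matched on gene length the microRNA list lay at the percentile 0.145 and the small nucleolar RNA list at 94.1, so neither median score was above the middle 95% for its length. SNORA3 led the small nucleolar RNAs at 1360 (1152 to 1595), on 151 reads, in the highest of its 6 intervals, which lies on chromosome 8. SNORD12 followed at 1100.0 (894 to 1339), on 99 reads. With the mean over a symbol's intervals in place of the highest, the median of the small nucleolar RNAs was 134.

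Genes of basic cell functions had low H3K9me3 gene scores, which are not corrected for control reads. Of the 20 housekeeping genes 0 lay above the median of all symbols, and their median was 14.8 reads per kb, with EEF1A1, a translation elongation factor, at 9.57 (7.55 to 11.96) and SDHA, a subunit of succinate dehydrogenase, highest at 35.9 (34.1 to 37.9). The 85 ribosomal protein genes had a median of 17.8 with 7 above the median of all symbols, the 39 proteasome genes 15.2 with 3 above, the 76 genes of the respiratory chain and ATP synthase 18.9 with 13 above, and the 25 cell cycle genes 16.1 with 2 above. TOP2A, the topoisomerase of mitosis, scored 11.2 (10.0 to 12.5) and MKI67, the proliferation marker Ki-67, was highest of the cell cycle genes at 70.9 (67.9 to 74.0). PSMB1 scored 9.55 (8.18 to 11.1) and NDUFA1 7.15 (5.03 to 9.85). RPL10L, a retrogene expressed in testis, was the highest of the ribosomal list at 107 (85.2 to 132). Among the 25 genes of the H3K9 methylation machinery 22 lay below the median of all symbols, with a list median of 22.2. The 3 above it were ZNF274, itself a zinc finger gene of chromosome 19, at 285 (279 to 291), EHMT1 at 57.4 (56.5 to 58.4) and ATF7IP at 52.1 (50.9 to 53.4). EHMT2, the methyltransferase G9a, scored 13.3 (11.6 to 15.1). The medians of the ribosomal, proteasome, respiratory chain, cell cycle and housekeeping lists lay below those of all 10000 random lists, and that of the H3K9 methylation list at the percentile 0.12. By peaks the H3K9 methylation list was not called in any setting: 44% of its genes had one, at the percentile 77.3.

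Of the fixed reference genes, the methyltransferase SETDB1 scored 22.9 (21.4 to 24.5) and its partner TRIM28 scored 16.2 (13.2 to 19.6). The housekeeping genes ACTB and GAPDH scored 15.5 (14.2 to 16.8) and 12.6 (9.52 to 16.4). BCR and ABL1, the partners of the fusion typical of chronic myeloid leukemia, scored 23.2 (22.4 to 24.0) and 28.5 (27.7 to 29.3). The hematopoietic transcription factors MYB and GATA2 scored 16.4 (15.1 to 17.7) and 16.1 (14.1 to 18.4), and the stem cell factor receptor KIT scored 50.4 (48.9 to 52.0). RUNX1 scored 60.6 (60.1 to 61.0), over an interval of 1197 kb.

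Genes of the myeloid lineage had lower gene scores than genes of other cell types. The 26 myeloid and progenitor genes had a median of 24.1 reads per kb with 21 below the median of all symbols, and the list lay at the percentile 0.28 of random lists. CTSG, the granule protease cathepsin G, was highest at 106 (93.7 to 118), followed by CD33 at 83.0 (78.5 to 87.8), and IL3RA had 0 reads. IL3RA and CSF2RA lie in the first 5 Mb of X, where the median of 41 intervals of 1 kb or more was 0, and without them the list had a median of 25.2, at the percentile 0.42. The 115 genes of the T cell, B cell, erythroid, neuron, liver and muscle lists had a median of 48.0, and the difference of -23.9 lay at the percentile 0.27 of random pairs of lists. Among protein-coding symbols alone the myeloid list lay at 3.67, inside the middle 95%, whereas the difference from the other cell types was below all 10000 random pairs. By peaks the myeloid list was not called: 30.8% of its genes had one, at the percentile 26.0, and only in lists matched on gene length was this share low, at 2.08. Medians of the other lists were 45.0 for 16 T cell genes, 48.0 for 14 B cell genes, 34.3 for 20 erythroid genes, 43.8 for 25 neuronal genes, 56.4 for 20 liver genes and 61.3 for 20 muscle genes. All 6 lay inside the middle 95% of random lists, at percentiles of 53.7, 62.8, 14.6, 51.5, 87.2 and 93.4. The liver and muscle lists lay above it in lists matched on gene length, at 97.9 and 99.2, and against protein-coding symbols alone, at 99.3 and 99.8. The muscle list also did so with the correction for short intervals, at 98.6. NEFM and NEFL, neurofilament genes on chromosome 8, scored 293 (280 to 307) and 155 (145 to 165), and BLK, a B cell kinase on chromosome 8, scored 159 (157 to 162). AHSP, the hemoglobin-stabilizing protein of red cells, scored 285 (252 to 321) without a peak, and ACTA1, skeletal muscle actin, scored 155 (141 to 170) with its whole length in a peak.

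The imprinted, germline, taste receptor, defensin and HOX lists lay inside the middle 95% of random lists. The 24 imprinted genes had a median of 56.6 (percentile 88.9), led by ZNF597 at 163 (154 to 173) and ZIM2 at 113 (109 to 117), and H19 was lowest at 12.5 (9.94 to 15.6). The 20 germline genes had a median of 57.2 (percentile 88.5) with TEX101 highest at 130.2 (124 to 137), the 27 taste receptors 63.9 (percentile 97.1) and the 45 defensins 49.6 (percentile 79.6). The 39 HOX genes, which specify position along the body axis, had a median of 46.0 (percentile 63.2), with HOXD12 at 245 (224 to 268), HOXC13 at 179 (170 to 189) and HOXA13 at 9.69 (7.46 to 12.4). Against protein-coding symbols alone the imprinted, germline, taste receptor and HOX lists lay above it, at 99.3, 99.3, 99.96 and 97.8. In lists matched on gene length the imprinted and germline lists again lay above it, at 98.4 and 99.3, whereas taste receptors lay at 67.4 and HOX genes at 89.0, inside it. Taste receptors also passed it, at 97.54, when genes of chromosome 19 were left out, and at 98.6 without chromosome 8 and 60 to 90 Mb of chromosome 15.

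Core histone genes split into low and high scores. Their median of 32.7 over 72 genes lay at the percentile 0.76, with 16 genes below the 10th percentile of all symbols and 20 above the 90th. HIST1H2BM, HIST1H3F and HIST1H4L scored 368 (314 to 428), 367 (314 to 426) and 352 (293 to 418), and HIST2H2AA3 had 0 reads. The call for the list was lost when lists were shifted along the genome (percentile 19.4), among protein-coding symbols (35.1), among genes with a score above 0 (2.98) and with the list mean (92.8). Cancer-testis genes of the X chromosome had a median of 5.87 over 99 genes, below all random lists, and 32 of them had 0 reads. Among genes with reads the list lay at the percentile 76.9. MAGEB4 was its highest member at 123 (109 to 139). The 82 genes of families in near-identical copies had a median of 3.43, below all random lists, with 66 below the 10th percentile of all symbols and 11 with 0 reads. Mappability was not used here, so for these families and for the cancer-testis genes low scores and 0 reads do not tell a lack of the mark from reads that could not be placed. The same limit holds for other genes with few or 0 reads, among them the 6 core histone genes with 0 reads and ZNF705D.

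**Figure D4:**
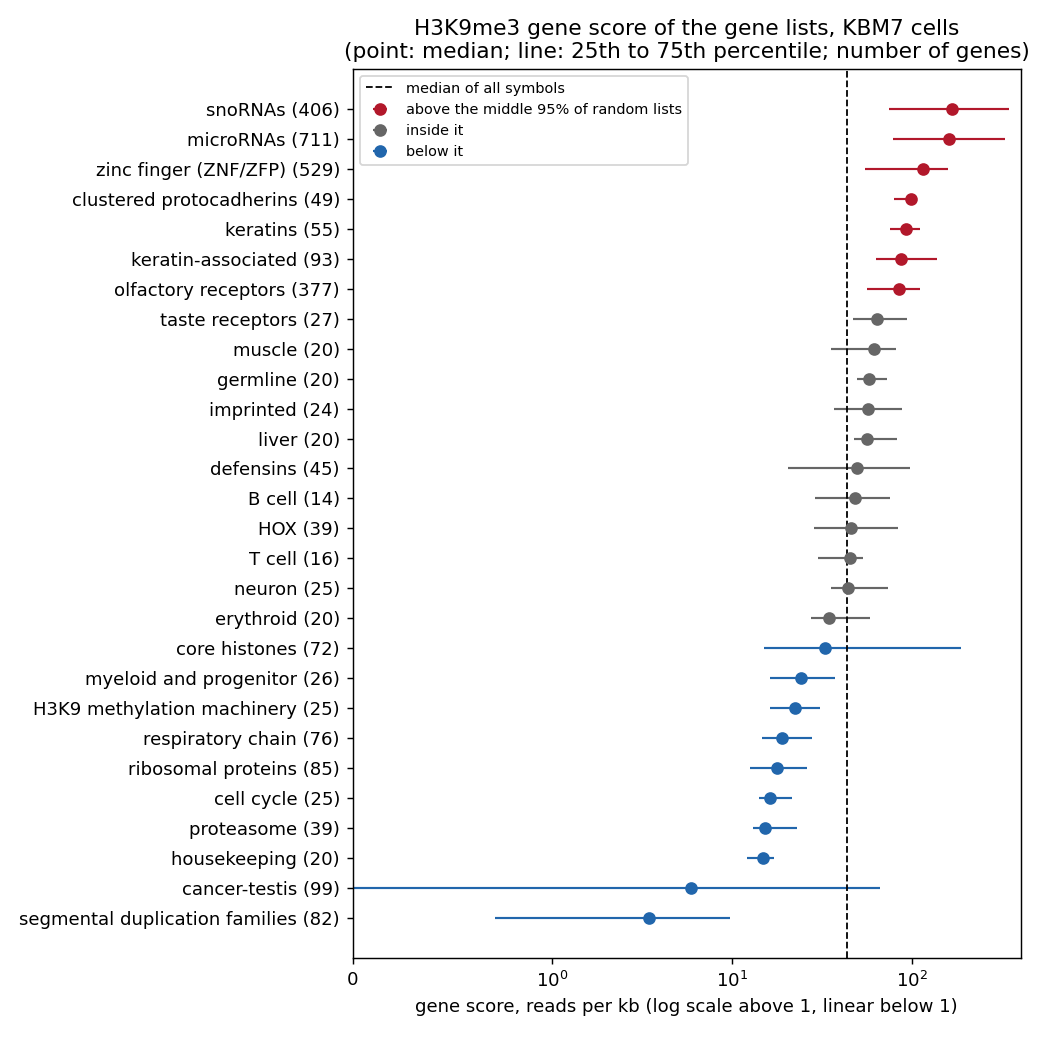
Points show the median gene score in reads per kb of each gene list, lines the 25th to 75th percentile over its genes and the dashed line the median of all symbols, on an axis that is logarithmic above 1 and linear below 1. Colours mark the 7 lists above the middle 95% of random lists and the 10 below it.

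Peaks were found in most zinc finger genes, protocadherins, keratins, and neuronal, germline and imprinted genes. At least 1 peak lay in 80.9% of zinc finger genes (exact binomial 77.3 to 84.2), 85.7% of protocadherins (72.8 to 94.1), 70.9% of keratins (57.1 to 82.4), 84.0% of neuronal genes (63.9 to 95.5), 90% of germline genes (68.3 to 98.8) and 66.7% of imprinted genes (44.7 to 84.4), against 36.8% of all symbols. These 6 shares lay above the middle 95% of random lists. Intervals of the alpha and gamma protocadherins are nested and share peaks, which the binomial interval does not take into account. Peaks were present in 5.88% of ribosomal protein genes (1.94 to 13.2), 10.0% of housekeeping genes (1.23 to 31.7), 12% of cell cycle genes (2.55 to 31.2), 15.4% of proteasome genes (5.86 to 30.5) and 15.8% of respiratory chain genes (8.43 to 26.0), below it. Olfactory receptors, with a high median score, had a peak in only 20.95% (17.0 to 25.4), below it as well, but against lists of the same gene lengths they lay above it, at 99.96. The call for neuronal genes was lost in lists of the same gene lengths (95.6), and that for germline genes when peaks within 1 kb of the start site were counted (96.5).

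Over the genome, peaks lay in gene bodies less often than random placements of the same peaks. Of 126923 peaks on chromosomes 1 to 22 and X, 47.6% overlapped a gene body (47.3 to 47.9), against 50.6% in 100 random placements (50.3 to 50.9), a ratio of 0.940. Windows of 1 kb either side of a transcription start site were overlapped by 4.42% of peaks (4.31 to 4.54), against 4.19% at random (4.06 to 4.35), a ratio of 1.05. The excess at start sites was lost with windows of 5 kb (ratio 1.01) and when placements left out empty stretches of 1 Mb or more (0.986).

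The gene score went with the peaks of the gene. Both come from the same H3K9me3 library, so this relation is no independent check of either. Symbols with a peak had a median score of 60.4 and those without one 31.0. Among genes of 1 kb or more the medians were 58.0 and 24.9. The 20 highest scores belonged to intervals of 0.054 to 0.535 kb, with scores from 1953 to 60102, and 5 of the 20 had a peak. AC098691.1 on chromosome 1 scored highest at 60102 (58493 to 61744), on 5289 reads over 0.088 kb, followed by AC091047.1 on chromosome 8 at 25730 (24587 to 26912), AC112777.1 on chromosome 12 at 17703 (17067 to 18357) and the microRNA gene MIR663 on chromosome 20 at 10806. None of these 4 had a peak, and none of the 20 was matched to a protein-coding gene. RN5-8S6 and RN5-8S2, each typed as a pseudogene, were also among the 20 and had no peak. Neither mappability nor the IgG library was used here, so these scores do not by themselves show the mark.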

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

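The alternatives by peak width, shifted lists, protein-coding symbols, chromosomes 8 and 15 left out, overhang correction and empty stretches were chosen after seeing the data. Alternatives that select peaks by significance or use the highest peak score were not run because the peak list used here gives neither. Of 467 alternative values for 72 results 404 stayed the same in direction and call or within the stated range, 19 lost and 14 gained a call, 11 moved and 19 reversed. Below the middle 95% of random lists in all 10 settings were the medians of the housekeeping, cell cycle, ribosomal, proteasome, respiratory chain, H3K9 methylation and near-identical copy lists. No list stayed above it throughout: 5 of the 7 lost the call with the list mean, which called 11 lists against 17, and microRNAs and small nucleolar RNAs (94.1) when matched on length. Peaks of 900 bp or wider numbered 72251, and the widest 10% (3000 bp or more) numbered 13274 and covered 73.2 Mb, by construction. The ratio of chromosome 8 to the other autosomes turned from below to above 1 with covered share (2.78) and with peaks of 900 bp or wider (1.32), as did chromosome 15 with covered share (1.55), since their peaks are wide; chromosome 19 went to 3.19. The start site ratio was 1.01 with 5 kb windows and 0.986 with empty stretches left out. Score percentiles changed side for cancer-testis genes with reads (76.9), core histones by the list mean (92.8) and microRNAs matched on length (0.145). Peak shares changed side for start site windows and for length-matched lists, in that order, in olfactory receptors (99.955 and 99.955), keratin-associated proteins (99.995 and 99.88), cancer-testis genes (94.56 and 71.92), core histones (99.895 and 97.57), microRNAs (100 and 99.865) and small nucleolar RNAs (100 and 100). The random lists they were first set against were not matched on length. Apart from the causes named, the cause was not tested. Depth limits short intervals most: those under 0.1 kb held a median of 13 reads.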

Other observations

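The 20 highest scores of intervals of 1 kb or more included the developmental transcription factors SOX17, NKX2-6 and OLIG3, beside 6 zinc finger genes. The family lists and tests in this part were chosen after the highest scores were seen, as were the test of read overlap on short intervals, that of interval length on chromosome 8, the use of a binomial interval for small RNA genes, the ratio of the 20 highest scores to their neighbours and the removal of SIX6 from the family test, each after the result it bears on. SOX17 and NKX2-6 on chromosome 8 scored 553 (527 to 581) and 469 (448 to 490) reads per kb, and OLIG3 on chromosome 6 scored 404 (378 to 432), each with its whole length in a peak. SIX6 on chromosome 14 scored 274 (257 to 291), and the lowest of the families was SOX4 at 5.13 (3.32 to 7.57). Of 155 genes in the families, 105 lay above the median of all symbols. A hypothesis is that these families as a class score high: without SOX17, NKX2-6, OLIG3 and SIX6 the other 151 had a median of 59.7, at the percentile 100 of 10000 protein-coding lists matched on length (middle 95% of these lists 26.6 to 38.7), as did the 152 with SIX6. Without chromosome 8 and the part of 15 the median of 145 genes was 57.5, again above all random lists. Peaks covered 25.1% of the gene bodies of the 151 on average, against a median of 8.15% in random lists. The hypothesis was found and tested on the same library, and whether other marks or the antibody play a part was not tested.

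The 9 HOXD genes had a median of 138 and 6 of them a peak, whereas medians were 32.8 for 11 HOXA genes (4 with a peak), 39.5 for 10 HOXB genes (0) and 42.3 for 9 HOXC genes (3). Ranges of HOXD (46.0 to 245) and HOXC (18.4 to 179) overlapped, and the difference between clusters was not tested. Immunoglobulin and T cell receptor segments also stood among the highest scores, and a hypothesis that they score high as a class met values on both sides. Their median overhang-corrected score of 52.4 over 535 segments lay at 96.56 among 10000 shifted lists, inside the middle 95%, and at 72.0 among lists of the same gene lengths. Without the correction their median of 101.8 lay at 99.85 among lists of the same gene lengths (middle 95% 81.1 to 98.0), so the outcome depended on the correction, and in the test chosen before its result was seen, that of shifted lists, they did not lie above the middle 95%.

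Scores on chromosome 8 were about 2 times those of other autosomes, here those other than 8 and 15. A gain of H3K9me3 only at marked regions is argued against by the ratio of 2.29 at the 10th percentile of scores (1.89 to 2.81, bootstrap over 5 Mb blocks), where it would be near 1, and shorter intervals by the ratio of 2.31 among intervals of 10 kb or more (2.22 to 2.44). An extra copy of the chromosome, for which a ratio near 2 at low scores as well was needed and one below 1.5 would have argued against it, may account for much of the pattern. The ratio was not 2 throughout: at the 25th percentile and the median it was 2.67 (2.24 to 3.04) and 2.32 (2.17 to 2.46), above 2, and at the 75th and 90th it was 2.04 (1.87 to 2.20) and 1.91 (1.77 to 2.16), so an extra copy alone was not shown to give the whole difference. Pooled over intervals of 1 kb or more, chromosome 8 held 92.4 reads per kb, 2.06 times the median of the other autosomes. Median scores of single autosomes other than 8 ran from 24.3 to 48.5, so the ratio also depends on the chromosomes compared. A gain of the mark over the whole chromosome stays open, since the IgG library was not analysed here.

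Short intervals scored high, with a median of 178 reads per kb under 0.1 kb against 34.4 from 1.6 to 10 kb. If reads are counted whenever they overlap an interval, a fixed overhang adds to its length, and a fit on short intervals gave an overhang of 204 bp (175 to 245). Division by length plus overhang lowered the ratio of intervals under 0.2 kb to those of 1 to 10 kb from 3.84 to 1.32 (1.26 to 1.35), between the bounds set for overlap as the whole cause and for its exclusion. The share of intervals under 0.2 kb with a peak was 7.98%, inside the range of 100 random placements (6.61 to 8.02), which had been set beforehand as arguing against more H3K9me3 at small RNA genes. Its binomial interval (7.39 to 8.60), a criterion added after the share was seen, runs past that range, and other values went both ways: in lists of the same gene lengths the share with a peak was high for microRNAs (15.05% against 11.8%, percentile 99.865) and small nucleolar RNAs (18.97% against 11.3%, percentile 100), whereas the microRNA score was low (0.145), so more H3K9me3 at small RNA genes stays open and overlap of reads is a likely part of the pattern.

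The 20 highest scores fell with the same correction, but their median kept a high rank. AC098691.1 fell from 60102 to 18091 and IGHVIII-38-1 from 2722 to 569. The median corrected score of the 20 lay at the percentile 99.97 of all symbols (99.96 to 99.98). This was above the 99th, the bound set for overlap of reads as the cause. The 20 were picked by the uncorrected score of the same reads, which favours a high percentile after correction. This test therefore could not exclude overlap of reads. For the 14 with an interval of 1 kb or more within 50 kb, corrected scores were 31.1 times those of these neighbours in the median (17.8 to 79.7). They ran from 2.30 times for RN5-8S2 to 192 for AC098691.1, and 13 exceeded 5 times. The 20 were picked by score, and the lowest corrected score among them was 569. This exceeds the 553 of SOX17, the highest-scoring symbol of 1 kb or more, so a ratio above 1 was fixed by the choice. Most of the 14 also had a single such neighbour, so a broad domain as the source of the whole score was not decided. Whether the surroundings are raised at all was not decided, with the neighbours at 1.68 times the median of all such intervals (1.21 to 2.80), and the other 6 had no such neighbour. Pile-ups shared with the control stay open as well, because 15 of the 20 had no peak and the IgG library was not analysed here.

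High scores without a peak were not limited to short intervals. Of 276 symbols of 1 kb or more in the top 1% of scores outside chromosome 8 and the part of 15, 25 (9.06%) had no peak. The highest of these were LINC00273 at 455 reads per kb and CR786580.1 at 429. ZNF671 at 243, ZNF460 at 174, TAS2R39 at 206 and GSX1 at 196 were among the others. The genes named here were chosen after their values were seen. Mappability and the IgG library were not used for them either.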
